A study of Mus musculus with 6 samples.

How the data were processed

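MicroRNA levels were measured by RT-PCR in the right lung of newborn mice at day 7 of life. The mice had been kept from before 12 hours of age in 95% oxygen for 7 days (hyperoxia, 3 samples) or in room air (3 samples). Per the labels' protocols, total RNA was reverse transcribed with the Megaplex rodent primer pools A and B, which prime many mature miRNAs at once, and the product went through 12 cycles of pre-amplification before the PCR. The authors deposited 1 table with a threshold cycle (Ct) per well and sample. The Ct is the PCR cycle at which the signal crosses a threshold, so a lower Ct stands for more RNA and 1 cycle for a fold of 2 at full efficiency. The table holds 768 wells, read here as 2 cards of 384 wells, 1 per primer pool. The instrument, the software and the Ct threshold were not given in the sources used here. A Ct of 40 marks a well without amplification, as the values show. Per the file headers, the authors also deposited the mean Ct of each group, its difference from a reference and a fold of hyperoxia over room air. Checked on the values, the difference between groups in that column equalled the one computed from the Ct values for 764 of 764 assays within 0.01 cycles, with a Ct of 40 counted as a measurement and with the U6 wells in row A of the first card as the reference for both cards. The fold is a ratio between groups, set by the authors with no test.

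Depth in this assay is the number of miRNAs detected. On the first card, 307 to 319 miRNA wells per sample had a Ct under 35, and on the second card 268 to 293. The number of samples limits the precision. The labels give the replicates as separate samples without saying that they came from separate animals or litters, so p-values here measure the spread between these samples, which may be partly technical.

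The following was computed from the Ct values with R 4.3.3 and limma 3.58.1. A Ct of 35 or more, or a blank well, was treated as not detected and left missing. Each sample's Ct values were subtracted from the mean Ct of the miRNA assays detected in all samples used, within each card (282 assays on the first card and 249 on the second), which gives a log2 relative abundance. The small RNA controls and a plant miRNA that mouse tissue lacks stayed out of that mean and out of the tests. The plant assay had a Ct of 40 in all 6 samples on both cards. An assay was tested where at least 2 samples of each group detected it. Hyperoxia was compared with room air by limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all assays tested and a threshold of 0.05 on the adjusted p. The estimated prior had 1.62 degrees of freedom, so each assay's own spread counted for much of its test. Single values such as the control RNAs were compared by an exact permutation test, whose smallest two-sided p with 3 samples against 3 is 0.1.

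The second-card values of room air replicate 1 and hyperoxia replicate 2 cannot both be measurements of their own sample. Of the 309 assays that amplified in both, 308 had the identical Ct, and over all 384 wells 382 values were identical, while on the first card the same samples shared 0 of 312 amplified values. Nothing in the labels shows to which sample these values belong. They were left out of both samples, so first-card assays were compared with 3 samples per group and second-card assays with 2. The design fixed before the data were examined had used all 6 samples on both cards; leaving these values out was decided after they were seen, and the fit as planned is given beside the result. A further point on the second card concerns names. The 105 assay names there that carry an assay number all match the number listed 3 wells later in the number column. With names as listed, the median Ct difference of the 5 small RNA controls between the cards was 0.72 cycles, against 6.96 cycles when the numbers were followed, so the names were used. The Ct values of 39 miRNA names found on both cards correlated across names by only 0.469 (Pearson) with names as listed and 0.152 by number; names are not independent replicates, and the identity of single second-card miRNAs stays uncertain.

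Lists of miRNAs (families, clusters, cell type markers, and miRNAs reported in hyperoxia or bronchopulmonary dysplasia from general knowledge) were fixed before the data were examined, 19 in all. They were tested with limma's camera, once with the preset correlation of 0.01 between members and once with an estimated correlation. Camera needs complete values, so it ran on the 282 first-card assays detected in all 6 samples and on the 16 lists with at least 3 members there. Assay names were matched to the lists by exact letter case. Second-card assays written with a capital letter, such as miR-669E, miR-466J, rno-miR-146B and rno-miR-409-3P, were therefore left out of their lists. This changes the counts and medians of those lists but not camera, which used the first card. The named miRNAs follow a rule fixed at the same time. It takes up to 15 miRNAs per direction with the largest log2 fold change past the threshold. Where fewer than 12 pass in a direction, it adds those with the smallest unadjusted p under 0.05, up to 12, said not to pass. It further takes up to 4 members per list with the largest change, always miR-34a, miR-21, miR-210 and the control RNAs, and up to 5 assays per direction detected in 1 group only. Gene neighbourhood was read from the RefSeq table of assembly GRCm38.p6, by symbol alone.

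The fit was tested on simulated data drawn from the 551 tested assays' means and within-group spreads, with 200 assays changed in each of 20 simulations. It recovered 29.8% of assays changed by 1 on the log2 scale, 61.6% of those changed by 2, 76.7% by 3 and 83.2% by 4, with 3.77% false calls among all calls. These shares hold only for 200 of 551 assays changed and for noise that is independent between assays. With few changed assays the adjustment is stricter and recovery lower, which was not simulated. Alternatives tried were other normalizations (control RNAs, U6 alone, median, quantile, none), Ct ceilings of 28, 32 and 40, undetected wells set at 35, other detection filters, limma-trend, array weights, the replicate number as a block, minor strands added to the lists and each sample left out. The fit first planned, with the shared second-card values kept in both groups, became an alternative once these values were seen. Alternatives added after seeing the data were those values kept in 1 group, the doubted samples left out of both cards and the first card only. Plate row G of both cards left out, the first card's mean for both cards and robust eBayes were also added then. A planned mean over both cards together was not run, since 2 samples have no second-card value.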

Results

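Newborn mice breathing 95% oxygen for their first 7 days are a model of the lung injury of oxygen-treated preterm infants, and the study asked which miRNAs change in such lungs. Mature miRNAs were read by RT-PCR in 3 right lung samples from hyperoxia and 3 from room air, on 2 cards per sample. The first card detected 307 to 319 miRNAs per sample and the second 268 to 293. Changes are log2 fold changes of hyperoxia over room air ± SE from limma, relative to the mean of the miRNAs detected on the same card. Assays of the first card rest on 3 samples per group and those of the second card on 2, because room air replicate 1 and hyperoxia replicate 2 shared 308 of 309 amplified second-card values.

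miR-34a, a miRNA induced by p53 that represses cell cycle and survival genes, came closest to the threshold. Its Ct was 20.99 ± 0.15 (SD, n = 3) in room air and 19.20 ± 0.17 (SD, n = 3) in hyperoxia. Relative to the other miRNAs of the card this was a log2 fold change of 2.55 ± 0.28, or 5.85-fold, with all 3 hyperoxia samples above all 3 room air samples and a limma adjusted p of 0.0723. Other miRNAs with small unadjusted p were miR-21, miR-221 and members of the miR-29 family on the higher side, and miR-335-3p, miR-503, miR-150 and miR-93 on the lower side, none of which passed over all assays.

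Of 551 miRNA assays tested by limma, 0 were higher and 0 lower in hyperoxia past the adjusted threshold, while 20 higher and 30 lower assays had an unadjusted p under 0.05 (27.55 assays in all would by chance). Among the 302 first-card assays, 68 (22.5%) had groups that did not overlap, where chance gives 10%; 19 of these were higher in hyperoxia and 49 lower. Assays are not independent, and another split of the 6 samples into 3 and 3 gave 58 such assays. With the shared second-card values kept in both groups, as first planned, 575 assays were tested, 0 passed, 35 had an unadjusted p under 0.05 and the adjusted p of miR-34a was 0.0758. The call on miR-34a depends on the setting. It passed in 7 of 28 alternatives, among them the first card tested alone (adjusted p = 0.0273) and plate row G of both cards left out (adjusted p = 0.0463), and its adjusted p ran from 0.00831 to 0.417 over all 28.

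On the higher side, miR-21, which is abundant in injured and fibrotic tissue, had a log2 fold change of 1.61 ± 0.33 (3.05-fold, limma adjusted p = 0.314). The minor strand of the same hairpin, miR-21#, was at 3.01 ± 0.78 on the second card (adjusted p = 0.446). miR-221, made in endothelium among other cells, was at 1.30 ± 0.31 (adjusted p = 0.333), and miR-132 at 1.68 ± 0.56 (adjusted p = 0.456). miR-147, induced in activated macrophages, was at 2.66 ± 0.71 (adjusted p = 0.373) at a low level, with a Ct of 31.2 ± 1.55 (SD, n = 3) in room air. The second-card assays miR-1937b and miR-1937c were at 1.86 ± 0.42 and 1.65 ± 0.42, but at -0.28 and 0.57 with quantile normalization. A further pair had very large values with wide spread. miR-331-5p lay in plate row G of the first card, whose readings scatter, and stood at 8.46 ± 1.59 with a value in 2 of the 3 hyperoxia samples. The assay of miR-322 in well P24 stood at 6.87 ± 1.61, and its Ct in hyperoxia was 22.0 ± 3.40 (SD, n = 3). The last 4 assays had a limma adjusted p from 0.314 to 0.446.

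On the lower side, miR-335-3p, from the hairpin within the imprinted Mest gene, had a log2 fold change of -3.20 ± 0.56 (limma adjusted p = 0.314); its Ct went from 20.1 ± 0.61 (SD, n = 3) in room air to 24.1 ± 1.48 (SD, n = 3) in hyperoxia. The other strand, miR-335-5p, named after its value was seen, was at -0.42 ± 0.29 (limma adjusted p = 0.689). miR-503, a cell cycle repressor of the miR-15 family, was at -1.60 ± 0.32, and miR-150, typical of mature lymphocytes, at -1.09 ± 0.27. miR-93, a paralog of the growth-promoting miR-17 cluster, was at -0.95 ± 0.24 and the heart-muscle miR-208b at -1.06 ± 0.25, with miR-208b near the detection limit (Ct 32.7 ± 0.18 in hyperoxia, SD, n = 3). rno-miR-219-1-3p was at -1.95 ± 0.59. On the second card, miR-669E was at -3.46 ± 0.47, miR-466J at -2.71 ± 0.35, rno-miR-25# at -2.57 ± 0.45, miR-145# at -2.0 ± 0.51, miR-1941-3p at -1.63 ± 0.33 and the erythroid hsa-miR-144 at -1.29 ± 0.32. Their limma adjusted p ran from 0.314 to 0.446. Of the named miRNAs, 13 second-card values moved by over 1.5 times when the shared values were kept in 1 group or both. Kept in room air or in hyperoxia, miR-669E was at -2.06 or -3.70, rno-miR-25# at -1.63 or -2.65, miR-1941-3p at -1.01 or -1.70, hsa-miR-144 at -1.34 or -0.81, miR-21# at 1.71 or 3.31 and miR-1937c at 1.08 or 1.68. Kept in both, miR-466J was at -1.80 and miR-145# at -1.33.

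**Figure D1:**
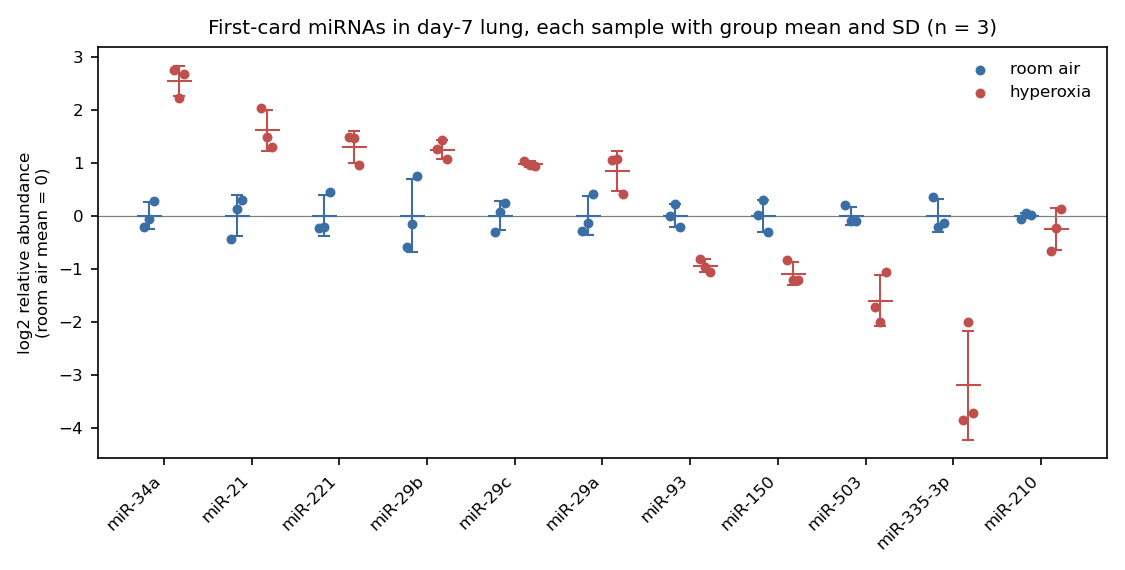
Log2 relative abundance of 11 first-card miRNAs in each sample (vertical axis, room air mean set to 0), with room air in blue and hyperoxia in red; horizontal bars are group means and error bars SDs of 3 samples. The miR-34a points lie 2.55 apart on average and do not overlap, while miR-210 (-0.26) and miR-29a (0.85) overlap between the groups.

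The miR-29 family, whose targets include collagens and other matrix genes, was the single list past camera's threshold. All 3 members had positive values: miR-29b 1.25 ± 0.40, miR-29c 0.98 ± 0.25 and miR-29a 0.85 ± 0.33. None of the 3 passed over all assays and all 3 passed when adjusted over the list alone. Camera gave an adjusted p of 0.00287 with the preset correlation. With an estimated correlation of 0.8 between the members the call was lost, at an adjusted p of 0.733. The other 15 lists tested had adjusted p from 0.163 to 0.913 with the preset correlation and from 0.733 to 0.962 with an estimated one. The 3 sequences are nearly alike, while the preset correlation treats the assays as almost independent. Their median stayed positive under every normalization tried, from 0.22 without normalization to 0.98.

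Among miR-34 and miR-449 family members, 4 of 7 tested were positive and 3 negative (2 positive and 5 negative with the control RNAs as reference). miR-34a alone passed when adjusted over the list alone, and 0 over all assays. miR-34b-5p was at 0.62 ± 0.54 (0.03 with the shared second-card values kept in hyperoxia, 1.00 in room air), whereas miR-449a and miR-449b, miRNAs of ciliated airway cells, were at -1.44 ± 0.67 and -1.03 ± 0.32. miR-449a was at -0.72 without hyperoxia replicate 2, and miR-449b at 0.18 with the shared second-card values kept in room air. Of the 4 other miRNAs known to respond to p53, 0 passed over all assays or adjusted over the list alone, with miR-215 at 0.46 ± 0.49 and miR-194 at -0.23 ± 0.29. With 1 sample left out these ran from 0.07 to 0.84 and from -0.44 to -0.12. The low-oxygen marker miR-210 was at -0.26 ± 0.28 (-0.48 to -0.06 with 1 sample left out) and did not pass (limma adjusted p = 0.79).

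Growth-related families had values on both sides of 0. In the cluster of miR-17 to miR-92a and its paralogs, 12 of 13 tested members were negative with a median of -0.43, 0 passed over all assays or adjusted over the list alone, and camera gave an adjusted p of 0.163 (0.733 with an estimated correlation). miR-93 and miR-106a (-0.60 ± 0.33) were the most negative members, and miR-25, at 1.92 ± 1.73, was the exception. Without hyperoxia replicate 2 miR-25 was at -0.098, and the list then passed camera with the preset correlation. The miR-15 family, with miR-16, miR-195 and miR-497, had 6 of 8 members negative and 2 that passed when adjusted over the list alone in opposite directions, miR-503 and the scattered miR-322 assay of well P24; miR-16 was at -0.70 ± 0.35 and did not pass. Its median was -0.38, its mean 0.39, and camera put its direction as down (adjusted p = 0.408). The let-7 family, which restrains growth, had 8 of 9 members positive with a median of 0.24, which was -0.32 with the control RNAs as reference and -0.52 without normalization; 0 passed, with let-7a at 0.61 ± 0.65 and let-7f at 0.53 ± 0.44. The miR-30 family had 5 of 7 negative, a median of -0.28 that was 0.04 with median normalization and 0.07 with the first card as reference for both, and 0 passing; miR-30c was at -0.34 ± 0.31.

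Among the lists of cell type markers, 1 member each passed in the endothelial and the smooth muscle and mesenchymal lists when adjusted over the list alone, miR-221 and miR-21, and 0 passed over all assays. miR-222, which shares a transcript with miR-221, was at 0.72 ± 0.32, while miR-126-3p, the miRNA of the endothelial gene Egfl7, was at -0.61 ± 0.37, and the smooth muscle miR-145 at -0.68 ± 0.23. Of 13 immune cell assays 8 were positive and 0 passed over all assays or adjusted over the list alone; miR-147, the myeloid miR-223 (0.94 ± 0.55) and miR-155 (0.94 ± 0.63) lay above 0 and miR-150 below it. The 10 epithelial assays lay between -0.49 and 0.20 with 0 passing (all 10 were negative with the control RNAs as reference or without normalization). Among them were miR-375 at -0.49 ± 0.49 (0.034 without hyperoxia replicate 2) and miR-203 at -0.29 ± 0.21. Blood content was read by 3 erythroid assays, of which 0 passed. miR-451 was at 0.71 ± 1.20 (-0.35 without room air replicate 1) and hsa-miR-144 below 0. Of 8 striated muscle assays 7 were negative and 0 passed, with miR-133a at -0.98 ± 0.46 and hsa-miR-206 at 1.31 ± 0.61 (0.26 with the shared second-card values kept in room air, 1.93 in hyperoxia). In the neural and neuroendocrine list 5 of 8 were positive and 0 passed; besides miR-132, its transcript partner miR-212 was at 1.22 ± 0.81 (0.39 with the shared second-card values kept in room air, 1.64 in hyperoxia) and miR-7b at 1.72 ± 1.24 (0.33 without hyperoxia replicate 1). For let-7, miR-30 and the epithelial, erythroid, striated muscle and neural lists the count of 0 holds over all assays and adjusted over the list alone. The liver miRNA miR-122 was at -0.69 ± 1.33 (0.77 without hyperoxia replicate 1, 0.95 with a Ct ceiling of 28). Leaving out 1 sample moved 19 named miRNAs by over 1.5 times, and none of the 19 passed. Among them were let-7a (0.14 to 1.17), let-7f (0.29 to 0.90), miR-30c (-0.56 to -0.19) and miR-222 (0.43 to 0.89). Others were miR-155 (0.46 to 1.502), miR-223 (0.48 to 1.45) and miR-126-3p (-0.96 to -0.35). Second-card miRNAs could not move in this check. Room air 1 and hyperoxia 2 give them no values, and leaving out any other sample leaves too few to test.

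In the imprinted Dlk1-Dio3 cluster, 42 of 63 tested members were negative and the median was -0.29 (35 negative and -0.14 with the first card as reference for both). Of the 63, 0 passed over all assays or adjusted over the list alone (camera adjusted p = 0.32). hsa-miR-127-5p was at -1.96 ± 0.51 (-1.31 with the shared second-card values kept in both groups). miR-380-3p was at -1.85 ± 0.61 and reached -2.87 over the alternatives. It lay near the detection limit, since a Ct ceiling of 32 left it detected in room air alone. miR-323-3p, in row G of the first card, was at 4.02 ± 2.55 (1.68 without room air replicate 1). In the cluster within an intron of Sfmbt2, 14 of 18 matched assays were negative, with a median of -0.44 and a camera adjusted p of 0.75. With the first card as reference for both, 10 were negative and the median was -0.15, and 11 were negative with median or quantile normalization. Of the matched assays, 0 passed over all assays or adjusted over the list alone. rno-miR-466b was at -6.08 ± 3.50 (-2.82 without room air replicate 1) and miR-297b-5p at 4.57 ± 2.96 (1.14 without hyperoxia replicate 2). Members written with a capital letter, among them miR-669E and miR-466J given above on the lower side, were not matched. The counts and the median are therefore not those of the full list. Of 30 tested assays of miRNAs reported in hyperoxia or bronchopulmonary dysplasia, 15 were positive and 15 negative (10 and 20 with the control RNAs as reference) and 0 passed over all assays. Adjusted over the list alone, 5 passed: miR-34a, miR-21 and miR-221 on the higher side, and miR-335-3p and miR-150 on the lower. That list may include work on these samples and is not independent evidence of direction.

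**Figure D2:**
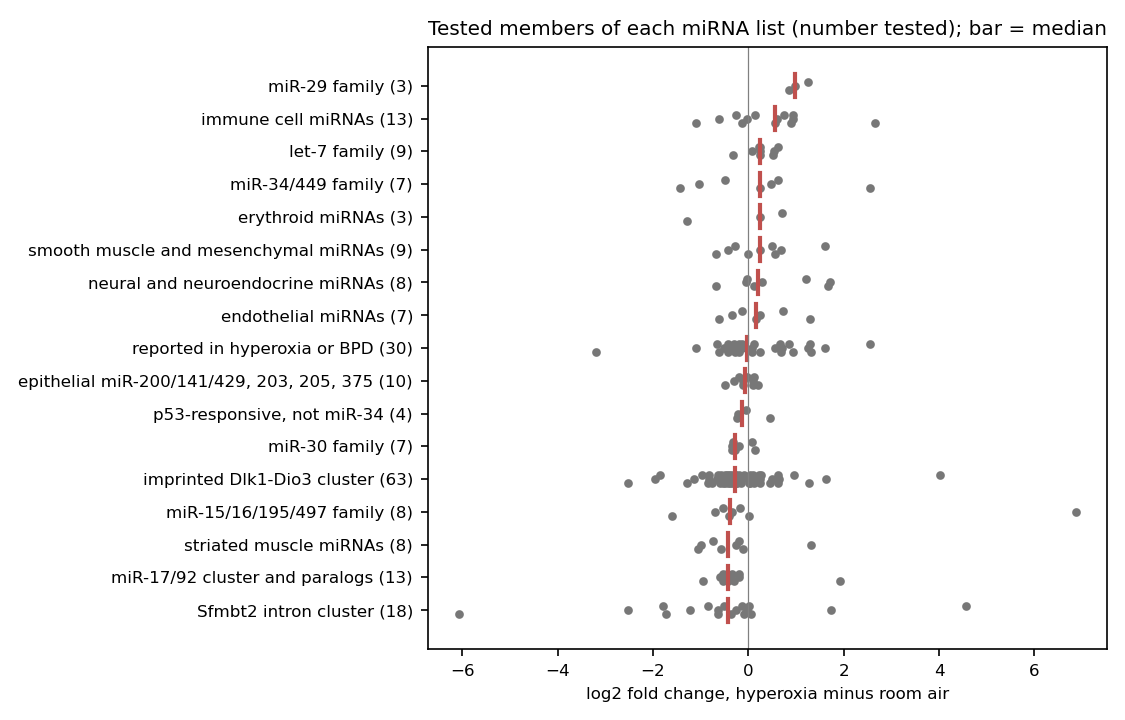
Log2 fold change of hyperoxia minus room air (horizontal axis) for each tested member of the lists with at least 3 tested members, 1 grey point per assay, with the number tested in brackets and the median as a red bar. The 3 miR-29 points lie between 0.85 and 1.25, and the other medians lie between -0.44 and 0.57.

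Plate row G of the first card scattered more than the rest of the plate. The median SD between samples of a group was 2.16 cycles there and 0.349 to 0.673 in the other rows. Besides miR-331-5p, it holds 2 of the 63 tested Dlk1-Dio3 assays and 2 of the 18 Sfmbt2 assays, and without these the medians of the lists were -0.29 and -0.56.

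**Figure D3:**
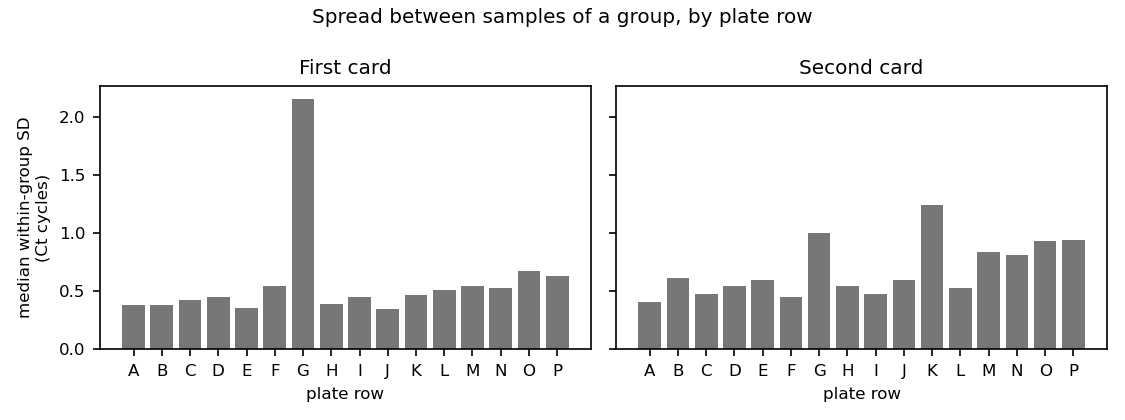
Median over tested assays of the SD between samples of a group, in Ct cycles (vertical axis), for each plate row (horizontal axis) of the first card (left, 3 samples per group) and the second card (right, 2 per group). Row G of the first card stands at 2.16, and the highest row of the second card, K, at 1.24.

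The reference chosen sets where 0 lies. On the first card the mean Ct of the detected miRNAs was 22.4 ± 0.30 (SD, n = 3) in room air and 23.1 ± 0.46 (SD, n = 3) in hyperoxia, 0.76 cycles later, with an exact permutation p of 0.1, the smallest that 3 against 3 allows. The samples were at 22.03, 22.48 and 22.60 in room air and 23.47, 22.61 and 23.31 in hyperoxia. Hyperoxia replicate 2 thus barely exceeded room air replicate 3, and the shift rests mainly on the other hyperoxia samples. U6, the nuclear spliceosomal RNA, was read by wells that disagreed: it was later by 0.43 cycles in row A and by 1.06 in row B, 0.75 on average. The other control RNAs differed as follows: snoRNA135 by -0.08 cycles, snoRNA202 by 0.04, U87 by -0.13 and Y1 by 0.41. Relative to the miRNAs, U6 was at 0.33 on the log2 scale in row A and -0.30 in row B (exact permutation p of 0.3 and 0.1). On that scale snoRNA202 was at 0.72 and U87 at 0.89 (exact permutation p of 0.1 each), snoRNA135 at 0.84 and Y1 at 0.35 (exact permutation p of 0.2 and 0.5). The median of all tested miRNAs was -0.12 as reported, -0.26 relative to the mean of the U6 wells, and -0.62 relative to the 5 control RNAs together or without normalization. Under the control RNAs, miR-34a was at 1.99 ± 0.41 and miR-21 at 1.04, while 1 of 9 let-7, 7 of 13 immune cell and 3 of 8 neural assays were positive. Without normalization these counts were 0, 4 and 3.

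Detection in 1 group only was rare. On the first card, miR-346 was detected in all 3 hyperoxia samples (Ct 25.6, 24.7 and 31.0) and in no room air sample, while 0 assays showed the reverse. With room air set at the ceiling of 35, miR-346 was at least 402-fold higher in hyperoxia, a limit that assumes its room air wells did not fail. Whether those wells, all at a Ct of 40, failed was not tested. That limit was 210-fold without hyperoxia replicate 1, 211-fold without replicate 2 and 1460-fold without replicate 3. The neighbouring rat miR-346 assay amplified in 1 hyperoxia sample (Ct 21.4) and in no other; it was looked at after its values were seen. On the second card, with 2 samples per group, miR-692 and 1 assay of miR-376c were detected in hyperoxia alone, and miR-295#, miR-698, miR-343 and hsa-miR-653 in room air alone. The shared values lay under the ceiling for all 6 of these. Giving them to room air ends the former 2 calls, and giving them to hyperoxia the latter 4. Another assay named miR-376c, on the first card, was detected in both groups, at -0.28 ± 0.25. A rat miR-343 assay on the first card had a fold of 7.0 in the authors' deposited table, the opposite direction. A Ct of 40 in some samples enters that fold.

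The authors' deposited table gives a fold for each assay relative to the U6 wells in row A of the first card. Of its 750 miRNA assays, 111 have a fold over 2 and 108 a fold under 0.5. A Ct of 40 in some but not all samples enters 58 of the former and 50 of the latter, and 11 of the former and 5 of the latter lie in plate row G of the first card. The largest fold in the authors' deposited table, 54000, is that of a miR-325 assay in row G of the first card. The 69 assays without amplification in any sample have a fold of 1.35 there, which is the 0.43 cycle difference of those U6 wells alone.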

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

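Over 1419 recomputed values of 55 named miRNAs, 1394 kept their direction and their side of the threshold, 8 moved past it and 17 changed sign, in 11 miRNAs. Several settings, among them limma-trend and robust eBayes, leave a log2 fold change as it was. No miRNA passed in the main fit either, so much of the 1394 was set in advance and does not measure stability. The count of higher miRNAs went from 0 to 1 with a Ct ceiling of 32 or 28, limma-trend, array weights, the first card only and row G of both cards left out (1 each, miR-34a), and to 2 when detection in 1 sample per group sufficed (miR-34a and miR-138#); without 1 sample it ranged from 0 to 1, the 1 being miR-322 in well P24 without hyperoxia replicate 1. No alternative gave a lower miRNA in limma. Assays of either direction at an unadjusted limma p under 0.05 were fewest without room air replicate 2, at 19 of 297 tested. They were most without normalization, at 124 of 551 tested. The adjusted p of miR-34a with 1 sample left out ran from 0.0775 to 0.178, and the cause was not tested. The miR-29 list passed camera with the preset correlation in all 28 alternatives (adjusted p 0.00118 to 0.0386), of which 20 moved its value, and with an estimated correlation in 0 (0.557 to 0.961). The number of lists past was 1 to 2 with 1 sample left out, adding the let-7 family without room air replicate 3 and the miR-17 cluster without hyperoxia replicate 2, and 2 without both doubted samples. On the first card, assays detected in 1 group only went from 1 to 3 with a ceiling of 32 (miR-346, miR-208b, miR-380-3p) and 2 with a ceiling of 28 (miR-154, miR-292-3p), because fewer wells then count as detected; miRNAs named here outside the naming rule were chosen after their values were seen.

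Signs that changed were all of values past no threshold, and their cause was not tested unless given. With the control RNAs as reference, let-7f was at -0.029 and miR-215 at -0.11. Without normalization, let-7a was at -0.15, let-7f at -0.23, miR-215 at -0.30, miR-222 at -0.037 and miR-451 at -0.048; here the whole scale moves down. With quantile normalization miR-1937b was at -0.28. miR-122 was at 0.95 with a ceiling of 28. With 1 sample left out, miR-122 ran from -1.54 to 0.77 (highest without hyperoxia replicate 1), miR-451 from -0.35 (without room air replicate 1) to 1.60, and without hyperoxia replicate 2 miR-25 and miR-375 changed sign, with ranges of -0.098 to 3.02 and -0.78 to 0.034. Without both doubted samples miR-25 was at -0.14, miR-323-3p at -0.20 and miR-375 at 0.063. miR-449b was at 0.18 with the shared second-card values kept in room air.

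With the replicate block, 0 miRNAs were higher and 0 lower among 301 first-card assays, 27 had an unadjusted p under 0.05 in limma, and 1 list passed. Same-numbered samples deviated from their group means with correlations of -0.336, -0.234 and -0.176, and no sample correlated best with its own number. These values give no sign of pairing by number but cannot exclude it. The deviations of a group sum to 0, so each sample has positive and negative correlations with the other group. Detection is the limit near the ceiling, where a difference of an assay seen in few wells rests on which wells stay under it.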

Other observations

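The tests weighed here were chosen after the results were seen, except that on the other members of the miR-322 cluster. Beyond the miRNAs described in the report, the X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450, which lie near each other in the reference annotation, had 11 of 12 tested assays below 0 in hyperoxia. The assay miR-450B-3P, written with a capital letter, is not among the 12. miR-351 was at -1.56 ± 0.49 (SE), its rat assay at -1.70 ± 0.56, miR-450a-5p at -0.83 ± 0.27 and miR-542-5p at -0.74 ± 0.36; none passed (limma adjusted p from 0.314 to 0.877 for the 11). These assays were chosen after the values of miR-503 and miR-351 were seen.

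A hypothesis is that the whole cluster was lower, with the high miR-322 assay as a misreading. For the 6 assays whose values had not been seen, the median was -0.57 with 6 of 6 below 0, at percentile 5.75 of 10000 random lists matched on level, just above the line of 5 set in advance. Varying the 6 values by their standard errors moved that percentile between 3.28 and 22.5, so the test leaves the hypothesis open. The 6 assays are also not independent of the values seen. Among them, miR-503# and miR-322# are other strands of seen miRNAs, and rno-miR-450a is a rat assay of the seen miR-450a. Members of 1 cluster may move together, which the random lists do not imitate, so the percentile may be too low. The first-card and second-card assays named miR-322 differed by 7.28 ± 1.65 (SE) on the log2 scale, which argues against 1 RNA read without fault by both. Their assay numbers differ (the second card's read 3 wells later), so they may read different strands, and a reading fault in well P24 stays open too.

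Large values gathered in plate row G of the first card. There 6 of 22 tested assays had a change of more than 16-fold, against 3 of 280 in the other rows (Fisher's exact test, two-sided p = 5.42e-06). The row was singled out by its median within-group SD of 2.16 cycles, against at most 0.673 in any other row of the card. Larger scatter by itself gives larger differences, and assays of 1 row are not independent. Neither that SD nor the Fisher p can therefore test a reading or loading fault or a response. The room air samples alone had a median SD of 1.04 there, above the 0.521 of the next row, but this is part of the same spread. A fault and a response to hyperoxia both stay open. What happened to the row is not recorded in the labels.

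For the higher miR-34a, 3 technical explanations were set against hyperoxia. The normalization is argued against as the whole cause, because the lowest value over 5 other normalizations was 1.79 ± 0.31 (SE), without any normalization. A single deviating sample is argued against too by the sample values, which on the log2 scale lay at 1.16 to 1.66 in room air and 3.61 to 4.13 in hyperoxia. The lowest value with 1 sample left out, 2.44 ± 0.33 (SE), restates this separation and is no further test. Less amplifiable RNA in hyperoxia would have raised its Ct, whereas the raw Ct was lower by 1.79 ± 0.13 cycles (SE), while the mean miRNA was 0.76 cycles higher. This is the same difference as the 1.79 without normalization, with an SE from the miR-34a values alone in place of limma's. The 2 arguments thus rest on 1 observation. A response of miR-34a to hyperoxia therefore stays as a hypothesis, found and tested on the same 6 samples, and litter, cage or dissection order could not be examined.

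The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. On the first card alone the real split called 1 miRNA and the highest other split 1, and 2 of the 10 splits gave as many. At an unadjusted p under 0.05 in limma the real split had 37 first-card assays and the highest other 36, and 68 against 58 assays had groups that did not overlap; that other split set room air 1 and 2 with hyperoxia 3. For lists with camera's preset correlation the real split gave 1 and the highest other 5, and 9 of the 10 splits gave as many. With an estimated correlation between members 0 lists passed in the real split; whether the other splits reflect correlated members or a structure of the samples was not tested. The split with 5 lists set room air 1 with hyperoxia 1 and 3. Over the other 9 splits the lowest camera adjusted p of the miR-29 family was 0.112, against 0.00287 in the real one. That family was followed because it passed in the real split, so this contrast favours the real split and is no support for it. Room air 1 and hyperoxia 2, the samples that share second-card values, also deviated together on the first card, with a correlation across 282 assays of 0.325, or 0.574 without row G. Room air 3 and hyperoxia 1, which share no second-card values, had 0.361 and 0.387. The deviations of a group sum to 0, so each sample must have a positive correlation with some sample of the other group. These correlations therefore cannot tell whether samples were mixed up, and assays are not independent replicates.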
